A study of Mus musculus with 10 samples.

How the data were processed

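Liver RNA of 10 mice was measured by sequencing of poly(A)-selected RNA, per the labels' protocols, which describe purification of mRNA on oligo(dT) beads, fragmentation and random-hexamer priming before library circularisation. The labels place the samples in 4 groups by genotype at Htra2 and by sex: 3 wild-type males, 3 heterozygous S400D males, 3 homozygous S400D males and 1 homozygous S400D female, all aged 2 months and of the C57BL6/N strain. No label gives a collection time, a litter or the origin of the wild-type animals.

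The deposited table holds, for each of 77712 transcripts and each sample, expected counts, FPKM and TPM as the authors computed them. The expected counts (estimated counts of reads per transcript, not normalised) were deposited by the authors without rounding. The FPKM values, which the authors scaled to transcript length and to the total of each sample, and the TPM values, which the authors scaled to a fixed sum per sample, were used only for alternative fits and for comparing the scaling of the samples. The submitters' processing notes name HISAT, Bowtie2 and the genome build GRCm38.p6; their versions, their roles and the program that estimated the counts are not given in the sources used here. Of the transcripts, 34387 carried curated and 43325 predicted RefSeq identifiers, and 2023 were further copies of a transcript at another position.

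Transcripts were summed to 19271 genes, of which 19214 were matched to a RefSeq gene and 57 were not. Of the nonzero gene sums, 94.5% lay within 0.05 reads of a whole number, and all sums were rounded to whole numbers before testing. Of the OXPHOS genes of mitochondrial DNA, listed under 26 names, 0 were analysed here. Reads shared between near-identical genes were divided by the authors' program, so values of single members of such families (Mup genes, Entpd4 and Entpd4b, Cyp4a12a and Cyp4a12b, haemoglobin genes) are uncertain. Strand use in the counting is not given in the sources used here.

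The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and edgeR's own filter on low counts by group, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The 9 males were fitted together with genotype as the only term, leaving 6 residual degrees of freedom, and 12427 genes were tested. From this fit came 3 contrasts between genotypes and the deviation of heterozygotes from the midpoint of the other 2 genotypes; the trend over 0, 1 and 2 alleles had the allele number as a numeric term. The female was compared with the 3 homozygous males in a fit of all 10 samples with 12954 genes, which assumes that a lone female varies as the males of each group do. Fold changes are log2 with the standard error (SE) of the fit, and levels are CPM (counts scaled to library size) with TMM factors, as mean ± SD over 3 animals. Genomic positions are those of GRCm38.p6, counted from 1.

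Before the data were examined, 39 gene lists were fixed, covering mitochondrial stress and metabolism, liver metabolism, the clock, immune and acute phase responses, markers of other cell types, sex-biased genes, neighbours of Htra2 and genes known to differ between C57BL/6J and C57BL/6N. Some genes stand in more than 1 list. Each list with at least 3 tested members (37 lists) was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For single members the p was adjusted over all genes and also over the list alone. The genes to be named were also fixed: Htra2; the 10 genes per direction with the largest change among called genes with a mean of at least 1 CPM in the higher group, no overlap of the groups and a regular gene name; up to 4 members per list past the threshold over all genes or over the list alone; with fewer than 10 calls, every called gene and the 5 genes per direction with the smallest p; and Nnt, Xist and Y-linked genes as checks of substrain and sex. Xist was not analysed here. Some genes that this rule chose are not reported here. Arntl, Npas2, Fasn, Scd1, Zpr1, Cish, Entpd4b, Csrp3, Klhdc7a, Hmgn2, Tuba8, Clec4f, Csf1r, Stab2, Cfd and Cela2a, and single genes named in a comparison where this rule did not choose them, were named after their values were seen.

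Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, DESeq2's size factors within edgeR, library size alone, other filters (none, and at least 1 CPM in 3 samples), the replicate number as a block, all 10 samples or only the compared groups in the fit, limma on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with at least 1 FPKM in 3 samples, an added requirement of an absolute log2 fold change of 1, and omission of each animal in turn. Alternatives chosen after seeing the data were a clock index (log2 of Arntl over Dbp) as a covariate, removal of a smooth trend on transcript length in each library, and all 6 male carriers against the 3 wild-type males.

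Each male comparison against wild type shares the same 3 controls, so the correlation of the fold changes was set beside 100 simulations of unchanged groups against these controls. The tests were checked on simulated counts for homozygous against wild-type males (12427 genes, 200 of them changed, 50 at each fold). With edgeR, 8 of 50 genes changed 1.5-fold, 31 of 50 changed 2-fold, 43 of 50 changed 4-fold and 50 of 50 changed 8-fold were recovered, with 5.71% false calls. DESeq2 recovered 14, 40, 43 and 50 of these with 19.2% false calls, and limma-voom 7, 32, 42 and 50 with 4.38%. The simulated counts varied independently between genes and libraries, so these rates may not hold for the real samples. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.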

Results

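The liver transcriptome was measured in 10 mice aged 2 months that differ at Htra2, the gene of the mitochondrial serine protease HtrA2/Omi. S400D replaces a serine of this protease by aspartate. Males were of 3 genotypes with 3 animals each, wild type (WT/WT), heterozygous (S400D/WT) and homozygous (S400D/S400D). The last animal was a homozygous female. Each library held 16240441 to 17264289 expected counts and between 14463 and 14882 genes with at least 1 count. Its 10 most abundant genes took 17.5% to 20.7% of the counts. The labels number the replicates without giving their origin, so p-values measure only the spread between these samples. The first principal component of the males (34.3% of the variance) placed the homozygotes at -48.3, -19.2 and -29.6 and the other 6 males between 1.3 and 32.3.

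Htra2 itself (gene 64704, GRCm38.p6 chromosome 6, 83051266 to 83054571) was at 14.0 ± 2.68 CPM in wild-type males (SD, n = 3), 15.9 ± 0.678 in heterozygotes, 14.9 ± 0.515 in homozygotes and 13.7 in the female. Its log2 fold change against wild type was 0.09 (SE 0.14, adjusted p = 0.792) in homozygotes and 0.18 (SE 0.14, adjusted p = 0.972) in heterozygotes. S400D changes the protein, so these gene-level values do not check the genotype labels. The Y-linked genes matched the sex labels. Ddx3y stood at 48.4 ± 0.959 CPM in wild-type and 49.7 ± 3.12 CPM in heterozygous males and at 0.0568 CPM in the female. Kdm5d was at 17.5, 19.5 and 16.1 CPM in wild-type, heterozygous and homozygous males, with 0 reads in the female, which allows up to 0.178 CPM (3 reads, counting error only). Nnt, a mitochondrial transhydrogenase that is disrupted in C57BL/6J and intact in C57BL/6N, was expressed in every group (135 ± 18.0, 118 ± 20.3, 167 ± 3.49 and 166 CPM).

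The comparison of homozygous with wild-type males asks what the S400D protease changes when no wild-type copy is left. Genes of fatty acid synthesis were lower in the homozygotes. All 19 measured members had negative fold changes (median -1.20, camera adjusted p = 1.31e-11, adjusted p = 0.514 with an estimated correlation), and 4 of them fell when adjusted over the list alone. These were Thrsp, a regulator of lipogenesis (log2 fold change -3.49, SE 0.84), the pyruvate kinase gene Pklr (-1.86, SE 0.55), malic enzyme Me1 (-1.10, SE 0.33) and ATP citrate lyase Acly (-1.20, SE 0.36). Thrsp was at 433 ± 203 CPM in wild-type and 38.4 ± 29.2 CPM in homozygous males. Homozygous male 1 lay apart from the others within this group, with Fasn at 69.6 CPM against 319 and 299 CPM and Scd1 at 112 CPM against 5827 and 3971 CPM. Cholesterol synthesis genes were lower in 22 of 24 cases (median -0.84, adjusted p = 2.05e-05, adjusted p = 0.778 with an estimated correlation), and 0 of them passed over the list alone.

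Genes that are higher in male than in female liver were lower in the homozygous males. Of 15 measured members 14 had negative fold changes (median -1.45, camera adjusted p = 1.31e-11, adjusted p = 0.418 with an estimated correlation) and 11 fell when adjusted over the list alone. Among them were the cytochrome P450 gene Cyp4a12b (-1.96, SE 0.35), Selenbp2 (-4.19, SE 0.96), the major urinary protein gene Mup3 (-1.07, SE 0.26) and the oxysterol hydroxylase Cyp7b1 (-1.75, SE 0.49). Cyp4a12b was at 85.9 ± 1.90 CPM in wild-type and 22.0 ± 8.40 CPM in homozygous males. Cyp4a12b and the Mup genes have near-identical copies, so the division of reads between copies is uncertain. Of 8 measured female-biased genes 6 were positive (adjusted p = 0.0591).

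**Figure D1:**
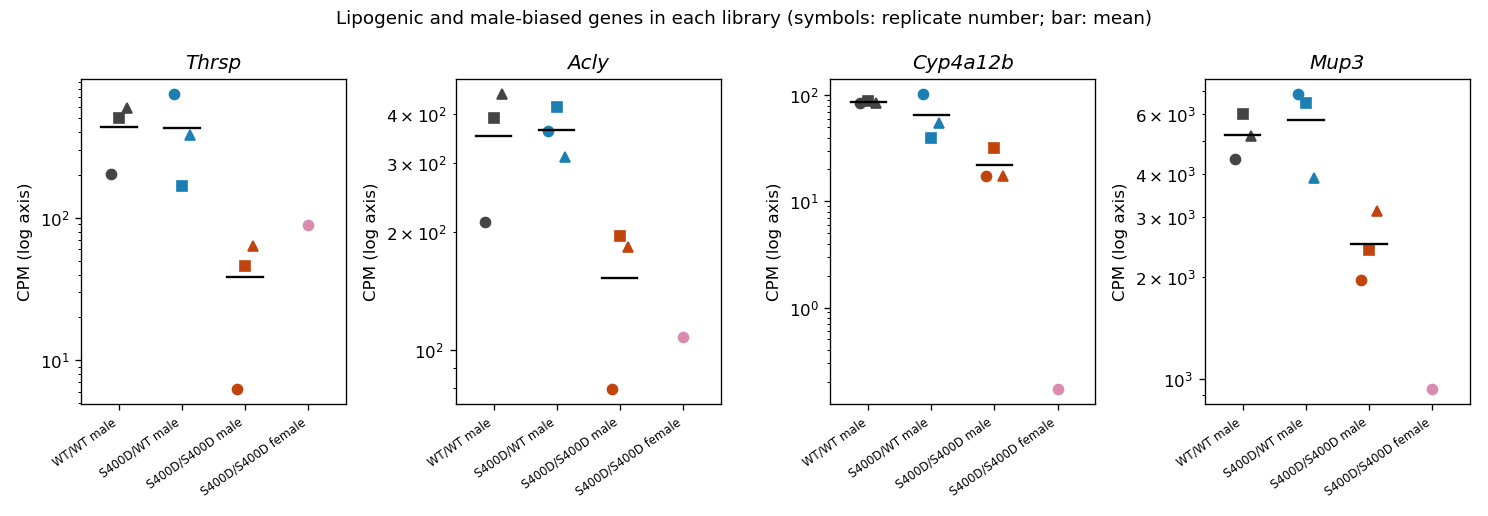
Levels of Thrsp, Acly, Cyp4a12b and Mup3 in each library, in CPM on a log axis, by genotype and sex. Points are animals, with the symbol giving the replicate number, and bars are means of 3 males; Cyp4a12b was at 85.9 CPM in wild-type and 22.0 CPM in homozygous males and at 0.170 CPM in the female.

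The genes of the circadian clock were shifted together. Of 19 members 14 were negative (median -0.78, adjusted p = 0.000226, adjusted p = 0.418 with an estimated correlation), and when adjusted over the list alone 9 fell and 3 rose. Per2 (log2 fold change -2.53, SE 0.58), Per3 (-3.65, SE 0.87), Bhlhe40 (-1.98, SE 0.46) and Dbp (-4.52, SE 1.16) were among those that fell. Arntl (3.13, SE 1.01), Npas2 (4.03, SE 1.45) and Nfil3 (2.06, SE 0.49) were those that rose. Arntl encodes BMAL1, which drives the positive limb of the clock, and Dbp and Per3 are its output and feedback genes. Single libraries did not follow genotype. Heterozygous male 2 had Arntl at 31.4 and Dbp at 6.02 CPM, while the other heterozygotes had Arntl at 1.18 and 2.57 and Dbp at 251 and 104 CPM. The homozygous female had Arntl at 1.59 and Dbp at 205 CPM, and the 3 homozygous males had Arntl at 17.7 to 37.9 and Dbp at 1.26 to 12.8 CPM. With a clock index (log2 of Arntl over Dbp) as covariate, chosen after seeing the data and built from members of this list, the median was -0.04 (adjusted p = 0.456). This index was 1.01 to 4.81 in homozygous and -5.86 to -5.18 in wild-type males, so it nearly coincides with these 2 groups. Its slope rests mainly on the heterozygotes (-7.61, 2.37 and -5.29), and the adjusted fold changes lose precision. A call lost with this covariate, here or below, therefore does not show that the clock accounts for it. This clock difference stands beside each gene group described for the homozygous males.

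**Figure D2:**
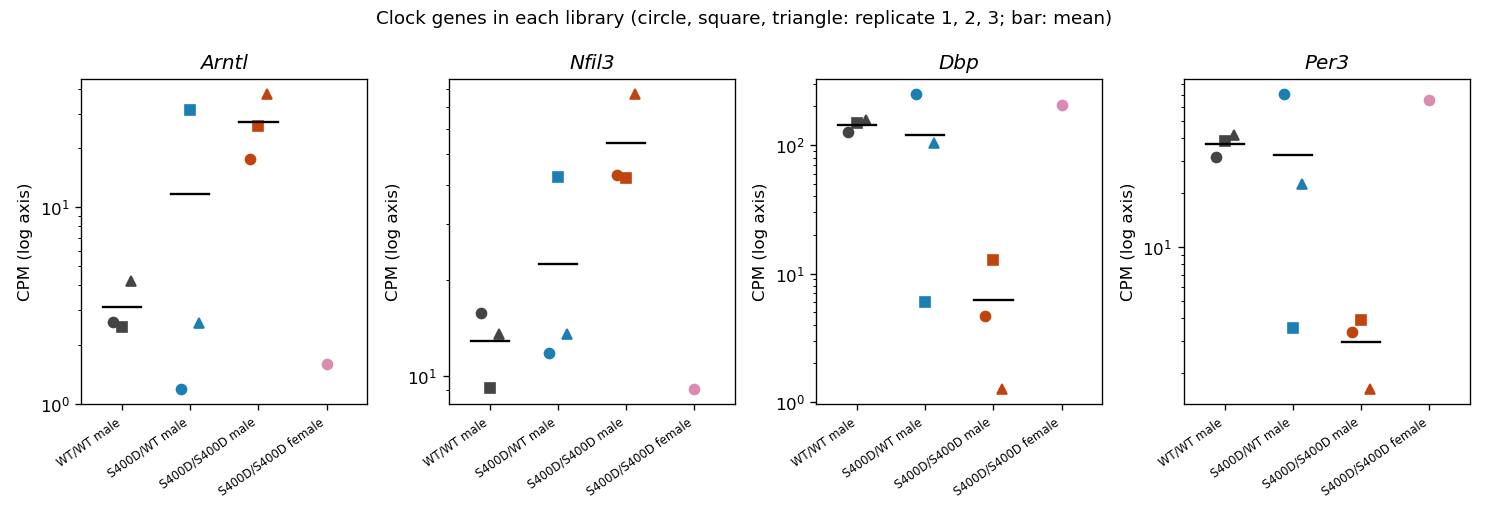
Levels of Arntl, Nfil3, Dbp and Per3 in each library, in CPM on a log axis, by genotype and sex. Points are animals, with circle, square and triangle for replicates 1, 2 and 3, and bars are means of 3 males; heterozygous male 2 (Arntl 31.4 CPM) lies among the homozygous males, and the homozygous female (Arntl 1.59 CPM) lies beyond the wild-type males (2.46 to 4.24 CPM), away from the homozygous males.

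Mitochondrial genes shifted by small amounts in many members. Of 75 nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) 72 were negative, with a median of -0.22 (adjusted p = 1.07e-09, adjusted p = 0.772 with an estimated correlation). Ndufb3 of complex I fell when adjusted over the list alone (46.8 ± 1.30 against 32.4 ± 2.78 CPM, log2 fold change -0.54, SE 0.10). Of 78 mitochondrial ribosomal proteins 67 were negative (median -0.17, adjusted p = 7.43e-07, adjusted p = 0.418 with an estimated correlation). The coactivator gene Ppargc1b fell over the list alone (-1.11, SE 0.29), while its list of biogenesis and dynamics genes did not pass as a whole (21 members, median 0.03, adjusted p = 0.954). Pdhb of pyruvate dehydrogenase fell over its list of 19 TCA cycle genes (-0.55, SE 0.13), a list with an adjusted p of 0.0857. Mitochondrial chaperones and proteases (20 members, median -0.12, adjusted p = 0.175), the mitochondrial apoptosis machinery (23 members, median -0.05, adjusted p = 0.733) and ATF4 target genes (27 members, median -0.18, adjusted p = 0.831) did not pass. Of the OXPHOS genes of mitochondrial DNA 0 were analysed here.

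Transcript length differed between the libraries. The mean length of the transcripts, weighted by their abundance (FPKM) and not by reads, was 1453 ± 9.4 bases in homozygous, 1312 ± 45.0 in heterozygous and 1349 ± 41.7 in wild-type males and 1449 in the female. Across 12427 genes, which are not independent, the fold change of homozygous against wild-type males correlated with transcript length (Spearman's rho 0.247). OXPHOS and cytosolic ribosomal protein transcripts are short, with median lengths of 444 and 441 bases. With the trend on transcript length removed, a setting chosen after seeing the data, the median of homozygous against wild-type males was -0.13 for OXPHOS (camera adjusted p = 0.0415), -0.10 for mitochondrial ribosomal proteins (0.0369) and 0.06 for cytosolic ribosomal proteins (0.0163), each with adjusted p = 0.933 with an estimated correlation.

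The heat shock, unfolded protein response, interferon and cell cycle lists were lower. Heat shock genes were negative in 13 of 14 cases (median -0.31, adjusted p = 0.00239, adjusted p = 0.734 with an estimated correlation), and the chaperone genes Hsp90aa1 (-0.44, SE 0.12) and Dnaja1 (-0.69, SE 0.19) fell over the list alone. The unfolded protein response of the endoplasmic reticulum was lower in 18 of 21 genes (median -0.19, adjusted p = 0.0265, adjusted p = 0.778 with an estimated correlation). Interferon response genes were lower in 23 of 28 cases (median -0.53, adjusted p = 3.45e-05, adjusted p = 0.778 with an estimated correlation). Cell cycle genes were lower in 15 of 18 cases (median -0.36, adjusted p = 0.0186, adjusted p = 0.772 with an estimated correlation), and cyclin E1 (Ccne1) fell over the list alone (-3.37, SE 0.69). Without homozygous male 1 the calls of cholesterol synthesis and interferon genes were lost (adjusted p = 0.095 for each), and without homozygous male 2 that of heat shock (0.185). The unfolded protein response lost its call without homozygous male 2 or 3 or wild-type male 2 (0.0932 to 0.251), and the cell cycle without homozygous male 1 or 3 or wild-type male 1 (0.0551 to 0.282). With the clock index as covariate, chosen after seeing the data, the calls of heat shock (median -0.16, adjusted p = 0.135), the unfolded protein response (0.02, 0.979) and the cell cycle (0.01, 0.796) were lost.

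Single genes of other lists also passed over the list alone in homozygous against wild-type males. The cell cycle inhibitor Cdkn1a rose from 1.82 ± 0.532 to 21.2 ± 10.6 CPM (3.52, SE 0.72). The autophagy gene Gabarapl1 (0.57, SE 0.13), the insulin signalling genes Foxo1 (0.71, SE 0.14) and Irs2 (0.67, SE 0.16), and Gadd45b (2.71, SE 0.77) and Klf6 (0.77, SE 0.22) rose. Glycogen synthase Gys2 (-0.97, SE 0.26) and Pfkfb3 of glycolysis (-2.25, SE 0.63) fell.

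Markers of other liver cell types were higher in the homozygous males. All 12 macrophage markers were positive (median 0.63, adjusted p = 3.38e-05, adjusted p = 0.772 with an estimated correlation), as were all 9 sinusoidal endothelial markers (median 0.56, adjusted p = 1.29e-05, adjusted p = 0.734 with an estimated correlation). Of 10 stellate cell and matrix markers 8 were positive (median 0.44, adjusted p = 0.0195, adjusted p = 0.778 with an estimated correlation). Lyve1, an endothelial hyaluronan receptor, rose over the list alone (3.77 ± 1.07 against 14.9 ± 8.45 CPM, 1.97, SE 0.37). The stellate call was lost without homozygous male 2 (adjusted p = 0.519) or wild-type male 3 (0.427). With the clock index as covariate the macrophage median was 0.25 (adjusted p = 0.0775), and the stellate call was lost at an almost equal median (0.45, 0.159). Library by library these markers did not follow genotype. The Kupffer cell gene Clec4f was at 51.2, 50.4 and 40.0 CPM in heterozygous male 1 and wild-type males 2 and 3 and at 93.1 to 112 CPM in the other 7 libraries, with wild-type male 1 at 112 CPM. Lymphocyte (7 members, adjusted p = 0.628), neutrophil (3 members, 0.831), cholangiocyte (6 members, 0.626) and erythroid markers (5 members, all negative, 0.220) did not pass. Of 16 adipose and pancreas markers 0 were expressed enough to be tested in males.

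The other lists did not pass the camera test between homozygous and wild-type males. Their adjusted p was 0.05 for xenobiotic metabolism (16 of 21 positive, just above the threshold), 0.124 for p53 targets (11 of 15 positive), 0.215 for fatty acid oxidation under PPARA (17 of 27 positive) and 0.220 for cytosolic ribosomal proteins (55 of 78 negative). It was 0.510 for immediate early genes (13 members), 0.732 for the urea cycle and zonation (17), NRF2 targets (24) and acute phase genes (22), and 0.744 for glucose metabolism (17) and autophagy (19). It was 0.999 for bile acid genes (16) and 0.945 for the Y-linked genes (4). The 19 measured neighbours of Htra2 on chromosome 6 had an adjusted p of 0.732. The 7 genes that differ between C57BL/6J and C57BL/6N gave 0.733, with Entpd4 falling over the list alone.

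**Figure D3:**
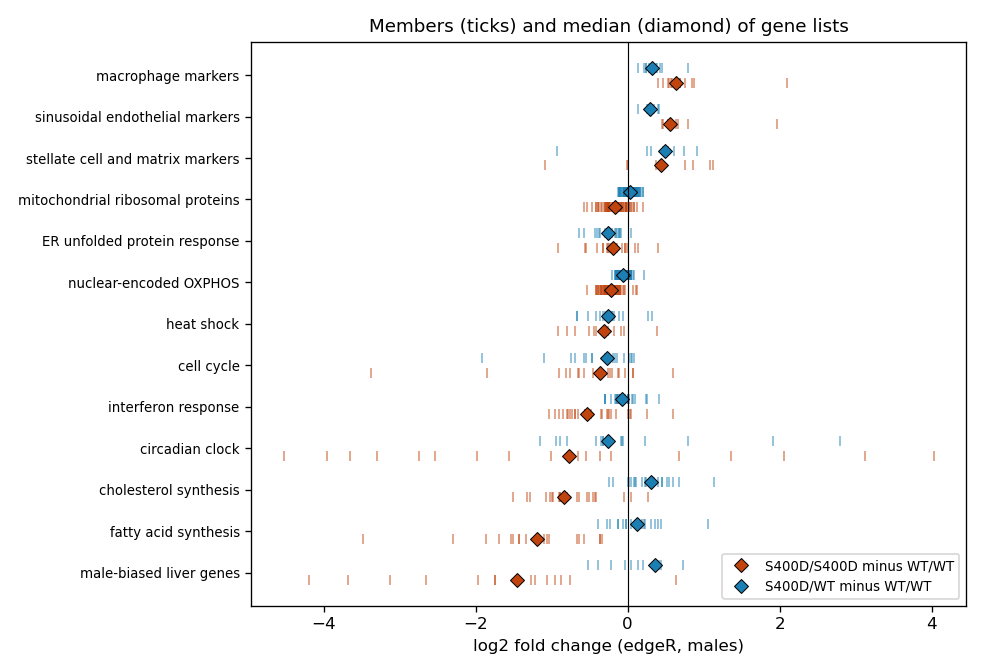
Log2 fold changes against wild-type males of the 13 gene lists past the camera threshold in homozygous males. Ticks are single genes and diamonds list medians, for homozygous and for heterozygous males; male-biased genes had a median of -1.45 in homozygotes and 0.36 in heterozygotes.

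Over all 12427 genes, edgeR called 0 genes between homozygous and wild-type males, with 1852 at an unadjusted p under 0.05 (848 higher, 1004 lower; chance gives 621.4). Limma-voom called 0 and DESeq2 307 (114 higher, 193 lower). The lowest adjusted p was 0.133. The smallest p values among the lower genes belonged to Krtcap2 (-0.80, SE 0.10), Bcl3 (-1.03, SE 0.13), Sel1l3 (-1.26, SE 0.17) and the NADPH oxidase Nox4 (-0.94, SE 0.15). Among the higher genes they belonged to Jchain of antibody-secreting cells (1.61, SE 0.25), Depp1 (1.44, SE 0.22), Nup62 (0.88, SE 0.15), Zfp36l2 (0.90, SE 0.16) and Chpf2 (0.57, SE 0.10). Without homozygous male 2 edgeR called 2 genes, Csrp3 and Klhdc7a, without wild-type male 1 it called 18 (14 higher, 4 lower), and without wild-type male 2 1121 genes were at an unadjusted p under 0.05. With the clock index as covariate that number was 461, but the index nearly separates the 2 groups, so lost precision alone could lower it.

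The comparison of heterozygous with wild-type males asks what a single S400D allele changes. Acute phase genes, which the liver makes in inflammation, were lower: 20 of 22 were negative (median -0.46, camera adjusted p = 2.65e-11, adjusted p = 0.466 with an estimated correlation). The orosomucoid gene Orm3 fell over the list alone (7.42 ± 4.72 against 0.538 ± 0.236 CPM, log2 fold change -3.78, SE 0.88), with single wild-type values of 2.37, 8.15 and 11.7 CPM. Entpd4, a Golgi nucleotidase (chromosome 14, 69337151 to 69366742), had 54, 214 and 54 reads in the wild-type males and 0 in each of the 7 animals with an S400D allele. A count of 0 allows up to 0.185 CPM there, and the wild-type levels were 3.13 to 13.8 CPM. Its near-identical copy Entpd4b (chromosome 14, 69555401 to 69584940) was at 27.4 ± 6.89 CPM in wild-type and 33.0 ± 1.08 CPM in heterozygous males, and the division of reads between both copies is uncertain.

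Several further lists were lower in heterozygotes by small amounts. Of the glucose metabolism genes 15 of 17 were negative (median -0.29, adjusted p = 8.27e-05), of urea cycle and zonation 16 of 17 (-0.26, 0.00016), of xenobiotic metabolism 16 of 21 (-0.29, 0.000876), of the unfolded protein response 20 of 21 (-0.26, 8.27e-05) and of heat shock 12 of 14 (-0.25, 0.000419). With an estimated correlation the adjusted p was 0.466 for each of these. Autophagy genes were negative in 18 of 19 cases (-0.14, 0.00334), the cell cycle in 14 of 18 (-0.27, 0.00238), the clock in 15 of 19 (-0.26, 0.0110), OXPHOS in 61 of 75 (-0.06, 0.0288) and NRF2 targets in 16 of 24 (-0.11, 0.0368). With an estimated correlation these had adjusted p = 0.499, 0.493, 0.466, 0.842 and 0.616. All 5 of these calls were lost without heterozygous male 2 (0.0731 to 0.578). Those of OXPHOS, the clock and NRF2 targets were also lost without wild-type male 3 (0.323, 0.0764 and 0.108), those of the cell cycle and NRF2 targets without wild-type male 1 (0.371 and 0.323), and that of NRF2 targets without heterozygous male 1 (0.144). The OXPHOS call was also lost with the clock index as covariate (0.0882), at an almost equal median of -0.06. Those of the clock and NRF2 targets were lost with the length trend removed (0.0805 and 0.0623), at larger medians of -0.33 and -0.19. In that setting OXPHOS kept its call, also at a larger median, which is given under the flagged results.

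Markers of other cell types and cholesterol synthesis were higher in heterozygotes. Lymphocyte markers were positive in 7 of 7 cases (median 0.73, adjusted p = 0.00212), stellate cell markers in 9 of 10 (0.50, 0.000855), sinusoidal endothelial markers in 9 of 9 (0.30, 0.00488), macrophage markers in 12 of 12 (0.32, 0.00669) and cholesterol synthesis in 22 of 24 (0.30, 0.0346). With an estimated correlation these had adjusted p = 0.466, 0.499, 0.616, 0.711 and 0.842. Clec4f of Kupffer cells was at 51.2 CPM in heterozygous male 1 and at 93.1 and 102 CPM in the other heterozygotes. Cholesterol synthesis turned direction without wild-type male 1 (adjusted p = 0.647) and lost its call without heterozygous male 1 or 2 (0.0839 and 0.501). The macrophage and endothelial calls were lost without wild-type male 2 (0.119 and 0.306), wild-type male 3 (0.682 and 0.123) or heterozygous male 3 (0.364 and 0.0945). The macrophage call was also lost without heterozygous male 2 (0.0582), and the stellate call without wild-type male 3 (0.159). With the clock index as covariate the medians of macrophage markers (0.20, adjusted p = 0.0515) and cholesterol synthesis (0.14, 0.182) were smaller and their calls lost. Male-biased genes (11 of 15 positive, adjusted p = 0.412) and fatty acid synthesis (11 of 19 positive, 0.415) did not pass.

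Over all genes edgeR called 0 genes in heterozygotes, with 521 at an unadjusted p under 0.05 (208 higher, 313 lower; chance gives 621.4). Limma-voom called 0 and DESeq2 7. The 7 were Bud13, Zpr1, Entpd4, Orm3, Ppl and Cish, all lower, and Mpp7, which was higher. Bud13, a splicing factor (chromosome 9, 46282976 to 46298783), was at 11.7 ± 0.961 CPM in wild-type and 5.61 ± 0.283 CPM in heterozygous males (edgeR log2 fold change -1.07, SE 0.16). Its neighbour Zpr1, a zinc finger protein (chromosome 9, 46273064 to 46282643), was at 92.8 ± 6.95 and 47.4 ± 11.3 CPM. The other genes with the smallest p in edgeR were Ppl (-1.52, SE 0.31), Card10 (-0.72, SE 0.15), Zfpm1 (-0.54, SE 0.11) and the clone-named 1810013L24Rik (-0.53, SE 0.10), all lower. Higher were Mpp7 (1.00, SE 0.17), Bcl6 (1.36, SE 0.33), Mdn1 (0.54, SE 0.13), Rbmx (0.46, SE 0.12) and Fgf21 (2.73, SE 0.73). With all 6 male carriers in 1 group against the wild-type males, a comparison chosen after seeing the data, edgeR called 0 genes, with 612 at an unadjusted p under 0.05. There Bud13 (-1.03, adjusted p = 0.170), Entpd4 (adjusted p = 0.661) and Zpr1 (-0.79, adjusted p = 0.912) did not pass. Between heterozygous and wild-type males the number at an unadjusted p under 0.05 was 1287 without wild-type male 1, 335 without wild-type male 2 and 259 without wild-type male 3.

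**Figure D4:**
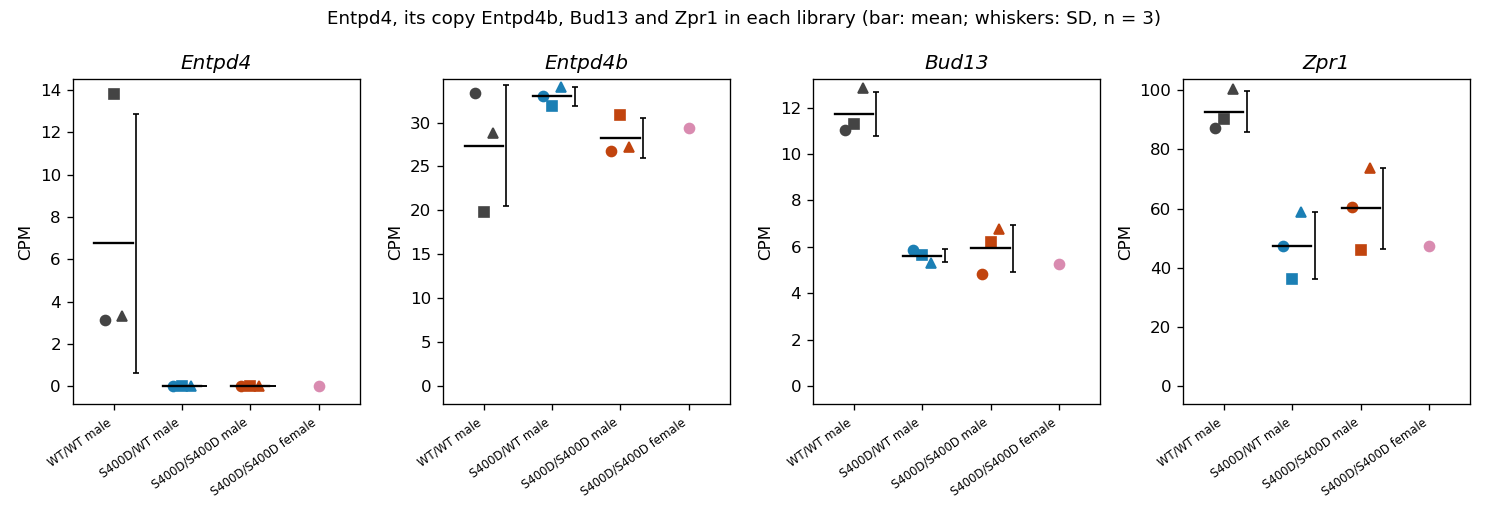
Levels of Entpd4, its copy Entpd4b, Bud13 and Zpr1 in each library, in CPM, by genotype and sex. Points are animals, bars means and whiskers SD of 3 males; Bud13 lies at 11.1 to 12.8 CPM in the wild-type animals and at 4.82 to 6.77 CPM in the 7 animals with an S400D allele.

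The comparison of homozygous with heterozygous males asks what the second S400D allele adds. Male-biased genes were lower in the homozygotes in 15 of 15 cases (median -1.32, camera adjusted p = 7.62e-13, adjusted p = 0.412 with an estimated correlation). Of these 11 fell over the list alone, among them Selenbp2 (-4.57, SE 0.98), Mup3 (-1.20, SE 0.26), Cyp4a12b (-1.57, SE 0.35) and Cyp7b1 (-1.95, SE 0.49). Fatty acid synthesis was lower in 19 of 19 genes (median -1.24, adjusted p = 7.62e-13, adjusted p = 0.412 with an estimated correlation). Of these 12 fell over the list alone, including the lipase gene Pnpla3 (-2.40, SE 0.56), Thrsp (-3.47, SE 0.84), Gpam (-0.60, SE 0.17) and Acly (-1.24, SE 0.36). Cholesterol synthesis was lower in 23 of 24 genes (median -1.20, adjusted p = 1.21e-08, adjusted p = 0.694 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell over the bile acid list alone (123 ± 7.74 against 35.2 ± 11.8 CPM, -1.80, SE 0.47).

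Drug metabolism and acute phase genes were higher in homozygotes than in heterozygotes. Of 21 xenobiotic genes 18 were positive (median 0.54, adjusted p = 1.76e-05, adjusted p = 0.412 with an estimated correlation). Of these 6 rose over the list alone, among them Sult1a1 (0.99, SE 0.19), Cyp2c37 (1.00, SE 0.20), Cyp3a13 (1.35, SE 0.28) and Cyp2b10 (4.33, SE 0.92). Of 22 acute phase genes 20 were positive (median 0.62, adjusted p = 7.17e-07, adjusted p = 0.694 with an estimated correlation). Here 6 rose over the list alone, with Serpina3n (1.26, SE 0.35), Crp (0.66, SE 0.18) and the metallothioneins Mt1 (3.53, SE 1.06) and Mt2 (4.31, SE 1.33). In glucose metabolism (median 0.31, adjusted p = 0.0378, adjusted p = 0.694 with an estimated correlation) 6 genes rose and 1 fell over the list alone. The glucose list lost its call without homozygous male 3 (0.25) or heterozygous male 2 (0.544). The coactivator Ppargc1a rose from 6.96 ± 2.02 to 16.7 ± 2.47 CPM (1.26, SE 0.23), and Irs2 (0.78, SE 0.16), Igfbp1 (2.54, SE 0.62) and Foxo1 (0.57, SE 0.14) rose too. The ATF4 targets Chac1 (1.84, SE 0.36) and Cth (0.91, SE 0.20) rose over a list that did not pass as a whole (adjusted p = 0.480). Over their lists alone Ei24 (0.60, SE 0.13) and Cdkn1a (2.84, SE 0.68) of the p53 targets, Gabarapl1 (0.66, SE 0.13) and Lyve1 (1.55, SE 0.36) rose.

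Mitochondrial ribosomal proteins were lower in 72 of 78 genes (median -0.20, adjusted p = 3.77e-09, adjusted p = 0.412 with an estimated correlation). OXPHOS genes were lower in 66 of 75 cases (median -0.17, adjusted p = 2.52e-05, adjusted p = 0.768 with an estimated correlation), and Ndufb3 (-0.61, SE 0.10) and Ndufa5 (-0.42, SE 0.09) fell over the list alone. With the trend on transcript length removed the OXPHOS median was 0.015 (adjusted p = 0.941) and that of mitochondrial ribosomal proteins -0.06 (0.0315, adjusted p = 0.834 with an estimated correlation). The mitochondrial proteases Oma1 (-0.45, SE 0.10) and Parl (-0.36, SE 0.09) fell over their list alone. The clock list did not pass (adjusted p = 0.0898), though 5 members fell over the list alone, among them Per3 (-3.42, SE 0.86) and Dbp (-4.25, SE 1.15). Heterozygous male 2 lay among the homozygotes in these genes.

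Immune lists went both ways between homozygotes and heterozygotes. Interferon genes were lower in 24 of 28 cases (median -0.47, adjusted p = 0.000384, adjusted p = 0.768 with an estimated correlation) and cytosolic ribosomal proteins in 60 of 78 (-0.10, adjusted p = 0.0329, adjusted p = 0.858 with an estimated correlation). Immediate early genes were higher in 12 of 13 cases (median 0.30, adjusted p = 0.0378, adjusted p = 0.561 with an estimated correlation) and autophagy genes in 13 of 19 (0.18, adjusted p = 0.03, adjusted p = 0.768 with an estimated correlation). Female-biased genes were higher in 7 of 8 cases (0.90, adjusted p = 0.0266, adjusted p = 0.694 with an estimated correlation). Sinusoidal endothelial (9 of 9, 0.32, adjusted p = 0.0329, adjusted p = 0.768 with an estimated correlation) and macrophage markers (12 of 12, 0.34, adjusted p = 0.0440, adjusted p = 0.858 with an estimated correlation) were higher. Endothelial, macrophage, female-biased and cytosolic ribosomal calls were lost without heterozygous male 1 (0.187, 0.602, 0.0565 and 0.541), heterozygous male 2 (0.0645, 0.0514, 0.0645 and 0.0521) or homozygous male 2 (0.0726, 0.122, 0.0675 and 0.228), and the macrophage call without homozygous male 3 (0.0825). Heterozygous male 1 is the heterozygote with Clec4f at 51.2 CPM. The interferon and autophagy calls were lost without homozygous male 1 (0.219 for each), autophagy without heterozygous male 2 (0.279), and immediate early genes without homozygous male 1 or 3 or heterozygous male 3 (0.0824 to 0.129). The clock index as covariate lowered the medians of immediate early genes to 0.10 (adjusted p = 0.514) and of macrophage markers to 0.05 (0.530). The endothelial (0.26, 0.147), cytosolic ribosomal (-0.10, 0.158) and female-biased calls (1.23, 0.0530) were lost there at a slightly smaller, an almost equal and a larger median. With the length trend removed cytosolic ribosomal proteins turned to a median of 0.12 (0.0352, adjusted p = 0.985 with an estimated correlation).

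Over all genes edgeR called 0 genes between homozygous and heterozygous males, with 2134 at an unadjusted p under 0.05 (1025 higher, 1109 lower). Limma-voom called 0 and DESeq2 544 (266 higher, 278 lower). The smallest p values among the lower genes belonged to Cyp2u1 (16.5 ± 2.64 against 4.19 ± 1.04 CPM, -1.97, SE 0.23, adjusted p = 0.104), Hes6 (-1.48, SE 0.20), the pseudogene Mup-ps16 (-3.56, SE 0.51), Faap100 (-1.14, SE 0.17) and Krtcap2 (-0.66, SE 0.10). Among the higher genes they belonged to Creg1 (0.81, SE 0.12), Tmem131 (0.55, SE 0.09), Saraf (0.54, SE 0.09), Stx2 (0.72, SE 0.12) and Slc25a33 (0.64, SE 0.10). Without homozygous male 2 edgeR called 6 genes, with Klhdc7a, Csrp3, Faap100 and Hmgn2 lower and Irs2 and Tuba8 higher. With the clock index as covariate 1037 genes were at an unadjusted p under 0.05.

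The trend over 0, 1 and 2 alleles asks which genes follow the number of S400D alleles. With 3 animals per genotype its slope rests on homozygous and wild-type males, so a gene can pass without heterozygotes lying in between. Bcl3, a regulator of NF-kB, went from 35.2 ± 6.66 to 23.6 ± 0.541 and 17.3 ± 0.661 CPM (log2 change per allele -0.51, SE 0.06, adjusted p = 0.108). Depp1, a target of FOXO factors, went from 50.6 ± 12.97 to 85.1 ± 13.8 and 137 ± 32.8 CPM (0.72, SE 0.10, adjusted p = 0.216). Both passed the threshold in 3 alternative fits, with library size alone and with limma at either pseudocount on FPKM. Bcl3 did so also without wild-type male 1. Next by p were Sel1l3 (-0.63, SE 0.11), Krtcap2 (-0.40, SE 0.07), Cabyr (-1.62, SE 0.28) and Naa80 (-0.29, SE 0.05) among the lower, and Jchain (0.81, SE 0.13), Zfp36l2 (0.45, SE 0.08), the fibroblast receptor Pdgfra (0.72, SE 0.13) and Nup62 (0.44, SE 0.08) among the higher. Over the list alone 10 clock genes, Ccne1 (-1.73, SE 0.32) and Ppargc1b (-0.55, SE 0.15) fell. Over the list alone 4 clock genes, Cdkn1a (1.84, SE 0.36), the macrophage receptor Marco (1.06, SE 0.28), the matrix gene Dcn (0.56, SE 0.16) and Lyve1 (1.00, SE 0.19) rose.

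The 13 lists past the camera threshold for the trend were those of homozygous against wild-type males. This match is built into the design and is no separate support. The smallest adjusted p belonged to OXPHOS (median -0.11 per allele, 1.07e-09), fatty acid synthesis (-0.58, 2.5e-09) and male-biased genes (-0.73, 7.67e-09). With an estimated correlation these had adjusted p = 0.758, 0.732 and 0.732, and the other 10 lists 0.732 or 0.758. Heterozygotes did not lie in between for fatty acid synthesis and male-biased genes, with medians of 0.12 and 0.36 against wild type. The same held for cholesterol synthesis (0.30) and mitochondrial ribosomal proteins (0.03). It also held for the unfolded protein response (-0.26 in heterozygotes, -0.19 in homozygotes) and stellate markers (0.50 and 0.44). For the other lists the heterozygous median lay in between. As against wild type, several of the 13 calls depended on single animals. Cholesterol synthesis and interferon genes lost theirs without homozygous male 1 (0.245 and 0.0653), heat shock without homozygous male 2 (0.0686) and the cell cycle without wild-type male 1 (0.311). The unfolded protein response and stellate markers lost theirs without homozygous male 2 (0.0907 and 0.266), wild-type male 2 (0.129 and 0.0541) or wild-type male 3 (0.0505 and 0.422). With the clock index as covariate the medians per allele of the unfolded protein response (-0.10 to -0.03, adjusted p = 0.362), the cell cycle (-0.18 to -0.13, 0.262) and mitochondrial ribosomal proteins (-0.08 to -0.03, 0.232) were smaller and their calls lost. Over all genes edgeR called 0 genes for the trend, with 1611 at an unadjusted p under 0.05 (791 higher, 820 lower) and 288 with the clock index as covariate. Limma-voom called 0 and DESeq2 171 (70 higher, 101 lower).

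The deviation of heterozygotes from the midpoint asks whether they lie off the middle of the other 2 genotypes. A list can lie off the midpoint and still in between. Interferon genes did so by their medians against wild type, -0.08 in heterozygotes and -0.53 in homozygotes. Heterozygotes lay above the midpoint in male-biased genes (15 of 15, median 0.84, camera adjusted p = 2.42e-09), fatty acid synthesis (19 of 19, 0.64, 7.4e-09), cholesterol synthesis (23 of 24, 0.75, 1.48e-07) and mitochondrial ribosomal proteins (69 of 78, 0.13, 1.33e-06). They lay below it in acute phase genes (21 of 22, -0.52, 6.44e-11) and xenobiotic metabolism (19 of 21, -0.24, 2.29e-06). With an estimated correlation the adjusted p was 0.362 for male-biased, mitochondrial ribosomal and xenobiotic genes, 0.405 for fatty acid synthesis and acute phase genes, and 0.615 for cholesterol synthesis. A shift of homozygotes alone also gives such a deviation, so it does not by itself show a change in heterozygotes. Against wild type, heterozygotes did not pass camera in male-biased genes (adjusted p = 0.412), fatty acid synthesis (0.415) or mitochondrial ribosomal proteins (0.182). They did pass in cholesterol synthesis, acute phase and xenobiotic genes. Over the list alone 6 xenobiotic genes were lower, with Sult1a1 (-0.79, SE 0.17), Cyp2c37 (-0.73, SE 0.17), Gstt3 (-0.72, SE 0.20) and Cyp3a13 (-0.89, SE 0.25). Chac1 (-1.45, SE 0.33), Cth (-0.73, SE 0.18), Ppargc1a (-0.99, SE 0.20) and the glutathione transferase Gsta2 (-0.99, SE 0.23) were lower too.

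Another 9 lists passed off the midpoint. Heterozygotes lay below it in glucose metabolism (11 of 17, median -0.17, adjusted p = 0.000677), urea cycle and zonation genes (13 of 17, -0.28, 0.00157), autophagy (17 of 19, -0.16, 0.00201), immediate early genes (11 of 13, -0.25, 0.0178), the unfolded protein response (17 of 21, -0.14, 0.0303) and female-biased genes (5 of 8, -0.56, 0.0303). With an estimated correlation these had adjusted p = 0.362, 0.362, 0.553, 0.362, 0.776 and 0.553. They lay above it in lymphocyte markers (6 of 7, 0.39, 0.0178), interferon genes (23 of 28, 0.17, 0.0303) and cytosolic ribosomal proteins (62 of 78, 0.06, 0.0303), with adjusted p = 0.613, 0.872 and 0.881 with an estimated correlation.

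All of these calls but that of the urea cycle and zonation were lost without a single animal. Without heterozygous male 2 those of glucose metabolism (0.106), autophagy (0.151), lymphocyte markers (0.151), the unfolded protein response (0.329), interferon (0.277), female-biased (0.106) and cytosolic ribosomal genes (0.0502) were lost, and without heterozygous male 3 those of immediate early genes (0.107), the unfolded protein response (0.250) and interferon genes (0.353). Without homozygous male 1 the unfolded protein response (0.375), interferon (0.635) and lymphocyte calls (0.140) were lost, and without wild-type male 2 the unfolded protein response (0.117), interferon (0.229) and cytosolic ribosomal calls (0.117). The female-biased and cytosolic ribosomal calls were also lost without homozygous male 2 (0.0542 and 0.179), heterozygous male 1 (0.146 and 0.888) or wild-type male 1 (0.172 and 0.319), and the lymphocyte call without wild-type male 3 (0.0629). The immediate early (median -0.17, adjusted p = 0.0723) and female-biased calls (-0.46, 0.0584) were lost at smaller medians with the clock index as covariate, and the cytosolic ribosomal call at an almost equal one (0.06, 0.0723). With the length trend removed the mitochondrial ribosomal median was 0.02 (0.139) and the cytosolic ribosomal one turned to -0.09 (0.182), while the unfolded protein response (-0.18, 0.061) and female-biased calls (-0.61, 0.061) were lost at larger medians.

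The first genes above the midpoint by p were Cyp2u1 (1.32, SE 0.18), Mpp7 (0.89, SE 0.14), Bcl6 (1.48, SE 0.27), Mup-ps16 (2.05, SE 0.38) and Hes6 (0.90, SE 0.17). Those below it were Saraf (-0.41, SE 0.08), Slc25a33 (-0.49, SE 0.09), the adenosine receptor Adora1 (-1.18, SE 0.23), Slc16a10 (-0.75, SE 0.15) and Wbp1l (-0.59, SE 0.12). Over all genes edgeR called 0 genes off the midpoint, with 1208 at an unadjusted p under 0.05 and 804 without wild-type male 3. Limma-voom called 0 and DESeq2 72 (21 higher, 51 lower).

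Changes against wild type were compared between heterozygotes and homozygotes. DESeq2 called 2 genes that were lower in both, Entpd4 and Bud13, where independent lists of that size would share 0.0951, and 0 that were higher in both. The figure of 0.0951 does not allow for the controls that both lists share. EdgeR called 0 genes in either. Across 12427 genes the fold changes correlated at 0.284, below the 0.502 (0.469 to 0.547 over 100 simulations) that unchanged groups give against the same controls. Their covariance was 0.0318 beside a simulated 0.0350, a difference of -0.0032. The 3 controls were not split between the comparisons. Since unchanged groups gave at least as much correlation and mean covariance, these values show no shared effect beyond that of the shared controls.

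The female homozygote was set beside the 3 homozygous males to describe this animal, since no other female was analysed here. With 1 library in this arm the spread is assumed from the males, so each p describes this animal and not females in general. Genes that are higher in female liver rose: all 14 measured members were positive (camera adjusted p = 2.01e-31, adjusted p = 0.0116 with an estimated correlation), and 11 passed over the list alone. The sulfotransferase gene Sult2a1 was at 63.7 CPM in the female and 0.0200 CPM in the homozygous males, and Sult2a2 at 36.2 and 0.0194 CPM. Sult2a7 was at 23.7 and 1.37 CPM (log2 fold change 4.10, SE 0.56) and the cytochrome gene Cyp2b13 at 325 and 0.434 CPM. These families share near-identical sequence, so single values are uncertain. Male-biased genes were lower in 15 of 16 cases (adjusted p = 1.61e-18, adjusted p = 0.13 with an estimated correlation), with Cyp4a12b at 0.170 against 22.0 CPM. The 4 Y-linked genes fell (adjusted p = 2.57e-05 with an estimated correlation). Slc25a33, a mitochondrial pyrimidine carrier, was at 7.72 against 22.9 ± 1.49 CPM (-1.56, SE 0.17).

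In this 1 female library, under the same assumption on its spread, the clock list lay higher (14 of 19, median 1.02, adjusted p = 0.000128, adjusted p = 0.243 with an estimated correlation), with Per3 (4.46, SE 1.01) and Dbp (5.03, SE 1.32) past the threshold over the list alone. Interferon genes (25 of 28, 0.56, adjusted p = 5.16e-07, adjusted p = 0.976 with an estimated correlation) and fatty acid oxidation genes (24 of 27, 0.51, adjusted p = 7.01e-05, adjusted p = 0.994 with an estimated correlation) lay higher too. So did xenobiotic metabolism (15 of 21, 0.22, adjusted p = 0.00445, adjusted p = 0.908 with an estimated correlation) and mitochondrial ribosomal proteins (54 of 78, 0.09, adjusted p = 0.0323, adjusted p = 0.976 with an estimated correlation), while heat shock genes lay lower (11 of 14, -0.36, adjusted p = 0.0246, adjusted p = 0.976 with an estimated correlation). EdgeR called 10 of 12954 genes. Higher were Sult2a1, Sult2a2, Sult2a7 and Cyp2b13, and lower were Ddx3y, Kdm5d, Eif2s3y, Uty, Slc25a33 and Cyp4a12b. DESeq2 called 104 (33 higher, 71 lower). Sult2a2 and Sult2a7 lost their calls without any 1 of the homozygous males, and Cyp4a12b without homozygous male 1 or 3 and with DESeq2's size factors. In a fit of only the 4 homozygotes edgeR called 7 genes, and Slc25a33, Uty, Cyp4a12b and Sult2a7 lost their calls. Of the 16 adipose and pancreas markers 2 were tested and did not pass, Cfd with 0 reads in the female and Cela2a at 0.454 CPM.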

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

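The tests of transcript length and of the Mup genes were chosen after the result was seen. The ratio of the authors' TPM to FPKM, which is the abundance-weighted mean transcript length in kilobases under another name, was at least 1.443 in the 4 homozygous libraries (1.443 to 1.461). It was 1.301 to 1.377 in wild-type and 1.276 to 1.363 in heterozygous males. It was flagged because it comes from FPKM and TPM, which the main fits do not use, and lay above its level in the wild-type libraries. These values derive from the same reads as the counts, and FPKM enters the limma alternatives. The ratio is therefore no independent evidence.

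The abundant and short Mup transcripts took 0.841% to 2.10% of the reads in homozygous and 2.87% to 8.53% in the other libraries. Without them every homozygous library still lay above every other one in abundance-weighted transcript length, by at least 26.9 bases, which argues against the Mup share as the whole cause. Other abundant transcripts were not left out. The albumin gene Alb took 8.64% to 10.3% of the counts in homozygous and 4.92% to 7.74% in the other libraries, and its part was not tested. For OXPHOS, removal of the length trend moved the median of homozygous against heterozygous males from -0.17 to 0.015, which makes a length trend a candidate cause, though part of that gap closed because heterozygotes went from -0.064 to -0.147 against wild type (camera adjusted p = 0.00146, 0.792 with an estimated correlation). Homozygotes went from -0.22 to -0.127 against wild type (interquartile range 0.156, camera adjusted p = 0.0415, and 0.772 before and 0.933 after with an estimated correlation), which leaves length and genotype open, and as all 4 homozygous libraries share the longer length, RNA quality, library preparation and biology cannot be told apart there.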

How the results depend on the processing

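The clock covariate, the transcript length correction and the grouping of all carriers were chosen as tests only after the results were seen. DESeq2 called 307 genes in homozygous and 7 in heterozygous against wild-type males, 544 in homozygous against heterozygous males, 171 for the trend, 72 off the midpoint, 104 in the female and 2 shared between heterozygous and homozygous changes. Against 0 calls with edgeR, the trend gave 2 with library size only, 2 with limma on log2(FPKM + 1) and 2 on log2(FPKM + 0.1). Leaving out 1 animal gave 0 to 18 calls in homozygous against wild-type males (18 without wild-type male 1), 0 to 6 against heterozygous males (6 without homozygous male 2) and 0 to 1 for the trend (1 without wild-type male 1). Limma-voom, DESeq2's size factors, both other filters, a fold requirement, fits with all 10 samples and fits of only the compared groups gave 0 calls in males. Of 72 list calls 0 were kept with an estimated correlation, 72 with DESeq2's size factors, 52 with the clock covariate (20 lost) and 64 with the length correction (5 lost, 3 turned). As the clock index nearly separates homozygous from wild-type males, losses with it can reflect lost precision. Over the omissions of 1 animal 561 calls were kept, 86 lost and 1 turned.

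Signs turned in a few results, and the cause was not tested. Htra2 ranged from -0.003 (without wild-type male 2) to 0.266 (without wild-type male 1) in homozygous against wild-type males and from -0.009 to 0.113 per allele without the same animals. Nnt in the female went to 0.002 with DESeq2 and 0.002 with its size factors, and from -0.01 to 0.004 without homozygous male 2 or 3. Entpd4 in homozygous against wild-type males was fitted at 4.35 with the clock index as covariate, which has no meaning at 0 reads in every carrier. Cholesterol synthesis in heterozygotes had adjusted p = 0.00015 without wild-type male 2 and 0.647, with its direction turned, without wild-type male 1. With the length correction OXPHOS (0.941) and cytosolic ribosomal proteins (0.0352) in homozygous against heterozygous males and the latter off the midpoint (0.182) turned. Of the Y-linked values between male groups 46 of 452 changed sign, with 0 called. No pairing by replicate number was seen: 2 of 9 pairs correlated over 0.1 (-0.438 to 0.195) and 2 of 9 libraries went best with their own number. With so few animals a group, this check cannot exclude that the numbers pair samples. With the replicate block edgeR called 0 genes in each of the 5 male comparisons, and 71 of the 72 list calls were kept, the exception being the list macrophage markers in homozygous against heterozygous males (adjusted p = 0.0525). Of 50 genes changed 1.5-fold in simulation 8 were recovered, so changes of that size were mostly beyond the precision of 3 animals a group. The simulated counts varied independently between genes and libraries, without the sample structure described below. Sensitivity in the real samples may therefore be lower, also for larger changes.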

Other observations

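The tests of the clock, of the wider shift, of Entpd4 and of genetic background were chosen only after the results were seen, and the clock statistic, the rule for the wider shift, the reading of the homozygous female and the rule for the OXPHOS length result were rewritten after that. The splits of the samples were planned.

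Markers of macrophages and endothelium set 3 libraries apart. Heterozygous male 1 and wild-type males 2 and 3 had the macrophage growth factor receptor Csf1r at 26.8, 28.2 and 18.5 CPM and the endothelial scavenger receptor Stab2 at 33.0, 29.5 and 24.7 CPM. The other 7 libraries had Csf1r at 60.2 to 75.5 and Stab2 at 45.4 to 62.1 CPM. Wild-type male 1 was among the 7. Without it, edgeR called 18 genes in homozygous against wild-type males, among them the endothelial genes Stab1 (0.98), Clec4g (1.13) and Fcgr2b (1.43), all with adjusted p = 0.0492.

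The clock genes shifted in homozygous males, and on a scale with wild type at 0 and homozygous males at 1 the heterozygous males lay at -0.115, 1.027 and 0.228, a range of 1.142. The scale rests on 10 clock genes, without Arntl and Dbp, that were picked because they differed between homozygous and wild-type males over the list alone. Such a range within a genotype is consistent with a different clock phase at collection that is independent of genotype, and no label gives the collection time, while the homozygous female at -0.188 is a single animal of the other sex, so homozygosity by itself stays open. Outside the clock list heterozygous male 2 lay at 0.299 (0.162 to 0.45), beside left-out homozygous males at 0.428 to 0.758 and left-out wild-type males at 0 to 0.629. The homozygous female, 1 animal of the other sex, lay there at 0.383 (0.235 to 0.525). Both this female and heterozygous male 2 lie within the range of the left-out wild-type males. Neither position therefore decides whether clock phase is the whole cause, and the part of clock phase stays open.

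Entpd4, Bud13 and Zpr1 were lower in every animal with an S400D allele, a pattern noticed in the data. A chance division of reads between Entpd4 and Entpd4b at a fixed share is argued against. The pooled wild-type share of 19.2% predicts 87.3 Entpd4 reads in the lowest carrier library, where 0 were found. Without wild-type male 2, which alone had 41.1%, the share still predicts 42.5. The share was not fixed, however, and ran from 8.56% to 41.1% among the wild-type males. Both copies together stood at 32.1 to 36.5 CPM in wild-type and at 26.7 to 34.1 CPM in carrier libraries, ranges that overlap. An assignment of all reads to Entpd4b in carriers is therefore not excluded, and a loss of Entpd4 is not shown. Bud13 differed between homozygous and heterozygous males by 0.086 on the log2 scale, so its level did not follow the allele number, which could come from a background difference of the S400D line or from an effect complete with 1 allele. The labels name no wild-type littermates, so these cannot be told apart. Entpd4 is on the list, fixed beforehand, of genes that differ between C57BL/6J and C57BL/6N. It alone of 7 tested members passed over that list in homozygous against wild-type males, and Nnt of that list was expressed in every group. Bud13 and Zpr1 are neighbours on chromosome 9 and may not be separate observations. Neither they nor Entpd4 (chromosome 14) lie on chromosome 6 with Htra2. Among all genes 103 were lower and 102 higher in all 7 carriers than in all 3 wild types, where chance gives 103.6 per direction.

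The samples were also split in other ways. For the comparisons of 2 groups, 10 splits exist, too few for a share under 0.05. At an unadjusted p under 0.05 the real split of homozygous and wild-type males gave 1852 genes and the highest other split 1315 (1 of 10 splits as large), homozygous and heterozygous males 2134 and 1072 (1 of 10), and heterozygous and wild-type males 521 and 1873 (3 of 10). By calls the real splits gave 0 genes, reached by 10 of 10 splits each, and the highest others 0, 0 and 213. For the trend 7 of 100 splits gave at least the real 1611 genes (highest other 2376) and for the midpoint 14 of 100 gave at least 1208 (highest other 2498), so chance cannot be excluded. By calls 100 of 100 splits reached the real 0 in both, with 10 and 479 as the highest others. The split with 213 calls set heterozygous male 1 and wild-type males 2 and 3 against the other 3 animals, and the split with 479 calls also held these 3 together, which points to a structure of the samples other than genotype.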
